A study of Mus musculus with 6 samples.

How the data were processed

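Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in lineage-depleted bone marrow cells of C57BL/6 mice. These cells are enriched for haematopoietic stem and progenitor cells. There were 6 samples, 3 from wild-type mice and 3 from mice lacking Utx (gene symbol Kdm6a), a histone demethylase of the COMPASS-like complexes. The labels give the genotype and a number for each sample, and they do not say whether the samples came from separate animals. The p-values of permutation tests over samples therefore measure only the spread between these samples. Tests that count regions or genes hold no spread between samples, and their p-values do not measure it.

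The authors deposited 1 list of peak coordinates per sample, called separately for each sample, with chromosome, start and end and no other column. MACS2 and the mouse build mm10 are named, per the submitters' processing notes, with no version. The file labels carry a p threshold for the calls. The aligner, read filters, any shift of insertion sites and the handling of duplicate reads are not given in the sources used here. No read count, score or summit was used, so the depth behind each list is unknown, and no interval that needs depth was computed. The presence or absence of a peak was therefore the measurement, and a list can be longer because more sites were open or because the library was deeper or cleaner.

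Peaks of all 6 samples that shared at least 1 bp were merged into consensus regions, and a sample was counted as having a region where any of its peaks overlapped it. A region was called lost when all 3 wild-type samples and no knockout sample had a peak there, and gained in the opposite case. Peaks on unplaced contigs (36 to 46 per sample) entered the list lengths and the consensus regions and were not assigned to genes. Gene positions came from the RefSeq annotation of GRCm38.p6, the same assembly as mm10, with 21887 protein-coding genes. The annotation table used here carries no strand and no exons, so the planned promoter measure was replaced by peaks or regions within 1 kb of either annotated end of a protein-coding gene, and positions are described only as inside or outside a gene.

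Per-sample values were compared by two-sided exact permutation tests over the 10 splits of 6 samples into 3 and 3, for which the smallest possible p is 0.1. Similarity of peak lists was the Jaccard index, shared over united bases, with a one-sided exact permutation of the genotype labels. A total of 15 gene lists with 247 entries was fixed before the data were examined, covering ETS and GATA factors, blood lineages, chromatin complexes, interferon response, leukaemia genes and housekeeping genes. A region belonged to a list when it lay in or within 20 kb of a member. Lost and gained shares of each list were compared with those of the remaining regions among 62100 regions near any protein-coding gene by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 15 lists, per direction, at an adjusted p of 0.05. Because regions are not replicates of the genotype, each list was also compared with 10000 random gene lists matched on the number of regions per gene, with genes as the unit, where the smallest p that the draws can give is 2.0e-04. Of members whose 20 kb surroundings overlap, only the earliest listed was kept in that comparison. Odds ratios have 95% intervals from the log odds, and shares have Wilson intervals.

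Genes named in the text followed a rule: Kdm6a; the 10 lost and 10 gained regions that were widest in their own genotype, since the lists carry no score, each with the nearest protein-coding gene within 50 kb; from each list up to 4 members with the most lost plus gained regions; and Gata1, Gata2, Spi1, Ets1, Erg and Fli1. Some items that the rule takes are not reported here. Other members are named only as examples, and were chosen after their values were seen. Planned tests of 18 sequence motifs in lost and gained regions were not run because no genome sequence was used here.

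The procedure was tested on simulated peak lists for the comparison of wild type with knockout, made from 75920 regions with 2076 lost and 1000 gained regions and random dropout. It recovered 85.4% of the lost and 85.6% of the gained regions, where the dropout allowed 85.7%, and 99.7% of the called lost regions were true. Dropout was the same for every sample and region width, and each unchanged region started in all 6 samples. In the data only 41.0% of regions were in all 6 samples, and knockout lists were shorter. The simulation therefore does not test false losses from weaker knockout libraries. The list given extra lost regions was called, and 0 other lists were. Alternatives were leaving out each sample in turn, the widest 50% of peaks, the same number of peaks per sample, other definitions of a shared region, other distances to genes, autosomes alone and a replicate block. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.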

Results

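The data were 6 lists of open-chromatin peaks from lineage-depleted bone marrow progenitors, 3 from wild-type and 3 from Utx-knockout mice. Wild-type samples 1, 2 and 3 had 57405, 57917 and 57622 peaks, and knockout samples 1, 2 and 3 had 45260, 50249 and 44576 peaks. Sequencing depth is unknown for all of them. The only comparison in the design is knockout against wild type. According to the series title, the question concerned ETS and GATA programmes of transcription. The lists hold genes that encode ETS factors, and GATA factor genes with erythroid genes, not the regions that these factors bind. Without the motif tests, the list results do not answer that question directly.

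Kdm6a, which encodes UTX, lies on chromosome X at 18160862 to 18279936 in mm10 and had peaks in every sample. There were 4.67 ± 0.577 peaks (SD, n = 3) in or within 20 kb of the gene in wild type and 5.67 ± 0.577 (n = 3) in knockout. Of 6 consensus regions there, 3 had a peak in all 6 samples, 0 were lost and 1 was gained, inside the gene at 18177763 to 18178482. Peak positions outside the deleted part of a gene do not test its deletion, and the deleted exons are not given in the labels, so these values do not check the genotype.

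Peak lists were more alike within than between genotypes. Knockout lists were shorter, with 46695 ± 3097 peaks (SD, n = 3) against 57648 ± 257 (n = 3), a difference of -19.0%, and every knockout list was shorter than every wild-type list. They covered 27.9 ± 1.75 Mb against 33.1 ± 0.670 Mb. Their median peak was wider, at 433 ± 7.09 bp against 408 ± 4.16 bp, and a larger share of their peaks lay within 1 kb of an end of a protein-coding gene, 26.1% ± 1.17 against 22.3% ± 0.128 (n = 3 each). Each of these differences had a two-sided exact permutation p of 0.1, the smallest that 3 samples against 3 allow, so none could pass 0.05. The Jaccard index was 0.731 to 0.765 between wild-type samples, 0.736 to 0.759 between knockout samples and 0.527 to 0.599 across genotypes. The mean within genotypes exceeded the mean between them by 0.179 (one-sided exact permutation p = 0.1, again the smallest possible).

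**Figure D1:**
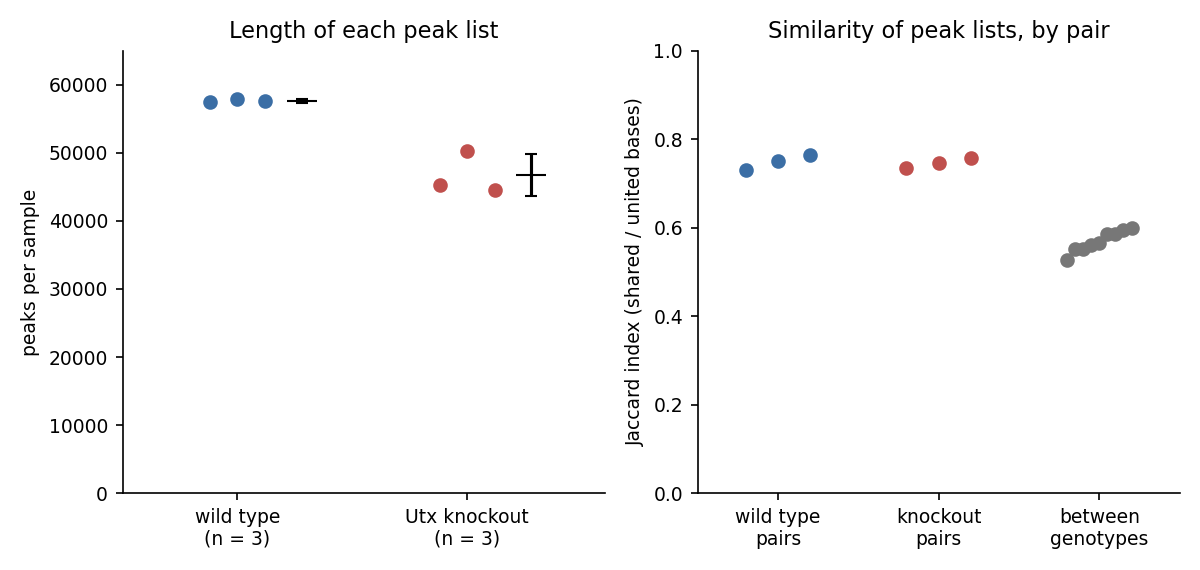
Left, the number of peaks in each sample (points are samples, the horizontal mark and bar are the mean and SD, n = 3); right, the Jaccard index of each pair of samples. The 3 wild-type lists hold 57405 to 57917 peaks and the 3 knockout lists 44576 to 50249, and pairs across genotypes lie at 0.527 to 0.599, below all pairs within a genotype.

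Regions near Zfpm1 and Lmo2 were among the widest of those lost in knockout cells, and regions near Lef1 and Sertad4 among the widest gained. Of 75961 consensus regions, 31159 (41.0%) had a peak in all 6 samples, 8042 (10.6%) were lost and 3566 (4.69%) were gained. Lost regions were 17.3% of the 46356 regions found in all 3 wild-type samples, and gained regions were 9.62% of the 37085 found in all 3 knockout samples. Their median widths were 444 bp for lost, 477 bp for gained and 740 bp for regions in all 6 samples. Lost regions made up 69.3% of the separated regions. With each sample limited to its widest 44576 peaks, which brings both counts together by construction, they made up 49.7% (4677 lost and 4740 gained).

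The widest lost region, with a mean peak width of 2863 ± 802 bp in wild type (SD, n = 3), lay inside Zfpm1, encoding the GATA1 cofactor FOG1, on chromosome 8 at 122320963 to 122324714. The next overlapped Smim1, which carries the Vel blood group antigen, at 2708 ± 493 bp on chromosome 4 (154023436 to 154026555), and lay within 1 kb of a gene end. After it came a region inside 3110082I17Rik on chromosome 5. The list went on with regions nearest to Aqp4, Hsph1, Lmo2, Sppl2b, Add3 and Mindy4. The Lmo2 region (chromosome 2, 103956665 to 103958842, 1966 ± 209 bp) overlapped an end of this gene, whose product joins GATA1 and TAL1 in erythroid complexes. The widest gained region overlapped an end of Sertad4 (chromosome 1, 192853993 to 192856813, 1950 ± 485 bp in knockout, n = 3). A gained region of 1559 ± 319 bp lay 2482 bp from Lef1, a transcription factor of early lymphocytes, on chromosome 3 at 131105980 to 131107814. The other widest gained regions were nearest to Otub2, Cplx2, Hmgcll1, Sema5a, Clasp1, C1ql3, Mctp1 and Spon1.

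Erythroid and megakaryocyte genes lost open regions in the knockout samples more often than other genes did, and B lymphoid genes gained them. Near the 28 GATA and erythroid genes, 74 of 230 regions (32.2%) were lost against 10.6% of the other regions near genes, an odds ratio of 3.99 (95% interval 3.02 to 5.27; Fisher's exact test, adjusted p = 1.63e-17), and 26 of the 28 genes had at least 1 lost region. The 2 without were the GATA factor genes Gata2 (0 of 4) and Gata3 (0 of 7). Zfpm1 lost 13 of 33 regions, the neighbouring beta-globin genes Hbb-bt and Hbb-bs 7 of 9 and 6 of 8 (6 of these lost regions are shared), and Ank1, encoding the red cell skeleton protein ankyrin, 6 of 12. Near 14 megakaryocyte and platelet genes, 21 of 95 regions (22.1%) were lost (odds ratio 2.37, 1.46 to 3.86; Fisher's exact test, adjusted p = 0.00605), with 6 of 11 at Rab27b, 3 of 9 at Gp9, 3 of 9 at Vwf, which encodes von Willebrand factor, and 2 of 7 at F2rl2. Near 14 B lymphoid genes, 21 of 116 regions (18.1%) were gained against 4.03% elsewhere (odds ratio 5.27, 3.28 to 8.47; Fisher's exact test, adjusted p = 1.26e-07), and 11 of the 14 genes had a gained region. Ebf1, a B lineage transcription factor, gained 5 and lost 1 of 16, the recombinase gene Rag2 gained 4 of 10 and Cd22 gained 3 of 10, while Dntt gained 1 and lost 2 of 11.

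Open regions were lost less often than elsewhere near 3 lists. These were ETS family transcription factors (11 of 280, 3.93%; odds ratio 0.340, 0.186 to 0.622; Fisher's exact test, adjusted p = 4.48e-04), granulocyte and monocyte genes (8 of 189, 4.23%; odds ratio 0.368, 0.181 to 0.748; adjusted p = 0.00671) and B lymphoid genes (3 of 116, 2.59%; odds ratio 0.221, 0.0703 to 0.696; adjusted p = 0.00671). Etv6 lost 2 and gained 1 of 46 regions, Ehf lost 2 of 5, Elf3 lost 2 of 4, and Spib, an ETS factor of B and dendritic cells, lost 0 and gained 3 of 10. Among granulocyte and monocyte genes, Fcnb lost 3 of 8, Irf8 lost 1 and gained 1 of 15, Cebpb lost 1 of 11 and Itgam gained 2 of 17. A region without a peak in every wild-type sample cannot be lost, yet these totals count such regions. Against regions of the same wild-type width elsewhere, lost regions were 0.411 times the expected number (95% Poisson interval 0.205 to 0.735) for ETS genes. The ratio was 0.407 (0.176 to 0.802) for granulocyte and monocyte genes and 0.343 (0.0708 to 1.004) for B lymphoid genes. The last interval includes 1, so this ratio does not settle fewer losses near B lymphoid genes. All of these Poisson intervals take lost regions as independent and may be too narrow.

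Regions are not replicates of the genotype, so these tests describe regions. With genes as the unit, all 6 calls stood apart from 10000 random gene lists, with adjusted p values of 0.003 (GATA and erythroid lost), 0.0258 (megakaryocyte lost), 0.009 (B lymphoid gained and ETS lost), 0.0157 (granulocyte lost) and 0.01 (B lymphoid lost). Neighbouring members were counted as 1. For B lymphoid losses this left 11 genes, with 0.952% of their regions lost (median 10.9% in random lists). Dntt, with 2 of the 3 lost regions of that list, was left out, so this adjusted p does not cover the full list. The lower loss near ETS genes did not pass with the same number of peaks per sample (Fisher's exact test, odds ratio 0.50, adjusted p = 0.124), with the widest 50% of peaks (0.584, adjusted p = 0.332) or within 50 kb (0.766, adjusted p = 0.272), and was 0.533 (adjusted p = 0.00871) without wild-type sample 1. That near granulocyte genes ended in the exact test without wild-type sample 2 (0.599, adjusted p = 0.129) or 3 (0.556, adjusted p = 0.0607), with the same number of peaks (0.470, adjusted p = 0.217), the widest 50% (0.699, adjusted p = 0.825), 50% coverage of the region (0.604, adjusted p = 0.173) or 2 of 3 samples sufficing (0.681, adjusted p = 0.159). With the widest 50% of peaks, which leaves fewer regions, the odds ratios of lost regions were 2.34 for megakaryocyte and 0.130 for B lymphoid genes and no longer passed the exact test (both adjusted p = 0.0953), and the latter was 0.278 (adjusted p = 0.0517) by nearest gene.

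For the other lists, neither direction passed the test. Haematopoietic stem cell genes lost 21 of 202 regions (10.4%; odds ratio 0.968) and gained 5, with 4 lost and 1 gained of 20 at Mllt3 and losses of 3 of 5 at Slamf1 and 2 of 8 at Kit. Myeloid leukaemia genes lost 19 of 185 (odds ratio 0.955), including 5 of 34 at Cdk6, which also gained 1, 5 of 30 at Ikzf1, 2 of 26 at Bcl2 and 1 of 13 at Dnmt3a, which also gained 2. Polycomb and SWI/SNF genes lost 14 of 151 (odds ratio 0.853), with 4 lost and 3 gained of 56 at Arid1b and 3 lost of 9 at Ezh1, while Smarca4 gained 2 of 12. UTX/COMPASS complex genes lost 5 of 68 (odds ratio 0.662), 2 of them near Kmt2d and 2 near Dpy30. Dendritic cell genes lost 4 of 90 (odds ratio 0.388), all near Zbtb46, and gained 5, of which 4 were near Tcf4 and 1 near Zbtb46. T and NK lymphoid genes lost 1 of 57 (odds ratio 0.149, adjusted p = 0.071 by Fisher's exact test), near Prf1, and gained 4, with 3 near Cd2 and 1 near Lck. Leaving out wild-type sample 2 (0.126, adjusted p = 0.0239), knockout sample 2 (0.122, adjusted p = 0.0225) or knockout sample 3 (0.142, adjusted p = 0.046), or asking peaks to cover 50% of the region (0.135, adjusted p = 0.0367), brought this odds ratio past the threshold in Fisher's exact test, whereas it was 0.349 (adjusted p = 0.169) without wild-type sample 1, 0.233 (adjusted p = 0.0631) without wild-type sample 3 and 0.273 (adjusted p = 0.151) without knockout sample 1. With the widest 50% of peaks, gains near T and NK genes passed the exact test (odds ratio 6.07, adjusted p = 0.00758). Lost counts were 2 of 47 for mast cell and basophil genes, 4 of 76 for interferon response genes, 4 of 75 for housekeeping genes and 3 of 24 for stroma and endothelium. The last passed only without wild-type sample 3 (Fisher's exact test, odds ratio 3.16, adjusted p = 0.0351).

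**Figure D2:**
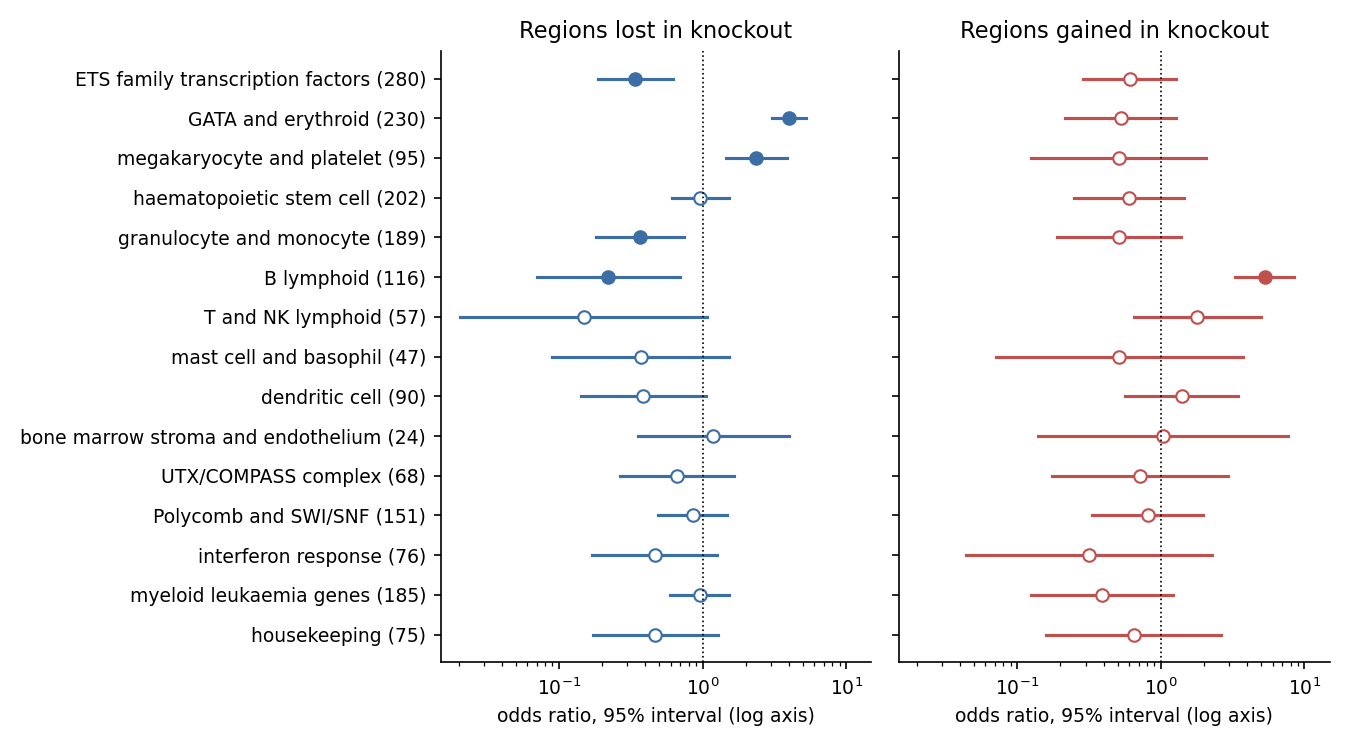
Odds ratios with 95% intervals (log axis) of lost regions (left) and gained regions (right) near each of 15 gene lists against other regions near genes; the number of regions of each list is in brackets and filled points passed an adjusted p of 0.05. GATA and erythroid genes stand at 3.99 among lost regions and B lymphoid genes at 5.27 among gained regions.

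The same lists were compared with the sample as the unit, as the share of each sample's peaks that lay near list members. A share takes account of list length only if shorter lists lose peaks evenly, and the share at gene ends differed between the genotypes. Small ratios are therefore not shown to be free of list length. Near GATA and erythroid genes lay 0.345% ± 0.0196 of wild-type peaks (SD, n = 3) and 0.204% ± 0.0106 of knockout peaks (n = 3), a ratio of 0.592, and near megakaryocyte and platelet genes 0.138% ± 0.00357 and 0.108% ± 0.0033. Near B lymphoid genes the shares were 0.103% ± 0.00202 and 0.197% ± 0.0164, a ratio of 1.92, or 59.3 ± 1.15 peaks in wild type and 92.0 ± 7.81 in knockout although the knockout lists were shorter. Shares near ETS factors were 0.388% ± 0.0157 and 0.423% ± 0.0107. The groups did not overlap for 9 of 15 lists, where chance gives 10% for a single list. All lists share the same 6 samples, and knockout lists differed in make-up, so 10% is no reference for the 9. Shares were higher in knockout for 5, namely B lymphoid, T and NK (ratio 1.37), dendritic cell (1.13), Polycomb and SWI/SNF (1.10) and ETS genes (1.09), and lower for 4, namely GATA and erythroid, megakaryocyte, mast cell (0.823) and haematopoietic stem cell genes (0.924). Of the 5, mean peak numbers were lower in knockout for dendritic cell (62.3 against 68), Polycomb and SWI/SNF (105 against 118) and ETS genes (197 against 224). They were higher for T and NK genes (41.3 against 37.3). Housekeeping genes, whose groups overlapped, had a share ratio of 1.08. Within 50 kb of a gene 6 lists stood apart, without ETS (a difference of 0.0187 in place of 0.035 percentage points), haematopoietic stem cell and mast cell genes (exact permutation p = 0.3 each), and 11 did with the widest 50% of peaks or by nearest gene, the latter again without mast cell genes. No list could pass adjustment in an exact permutation test of this size (smallest adjusted p = 0.167).

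**Figure D3:**
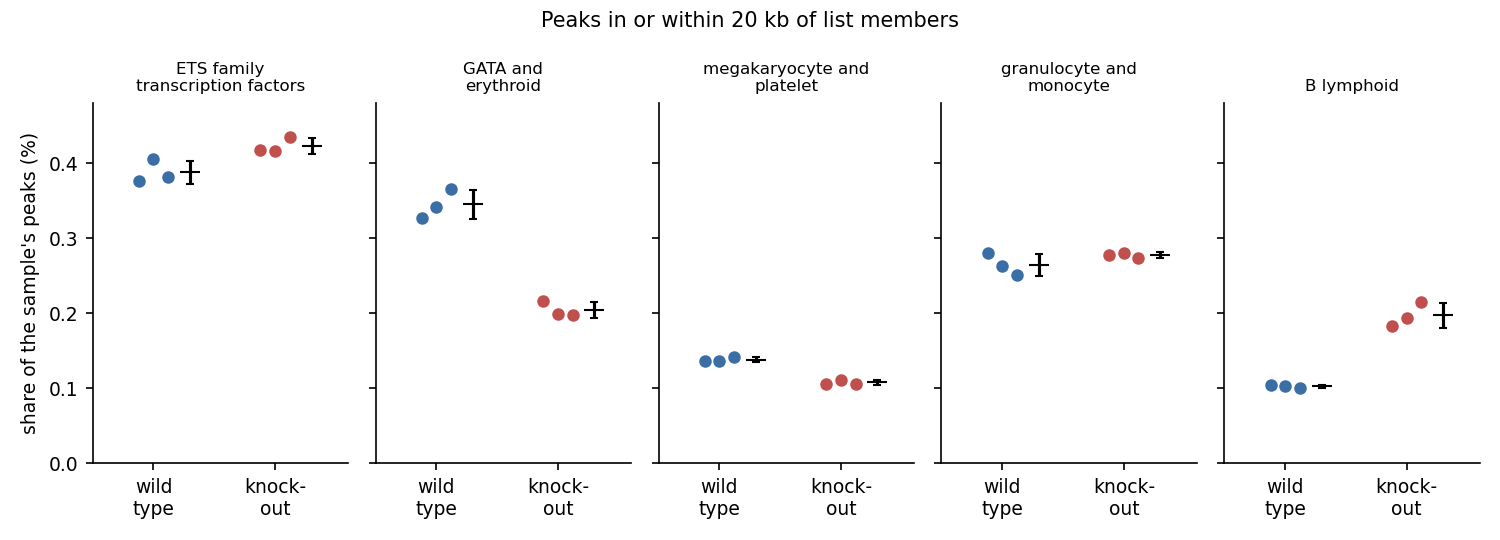
Share of each sample's peaks (%) in or within 20 kb of the members of the 5 lists with a call; points are samples, the horizontal mark and bar are the mean and SD (n = 3). Knockout samples lie below wild type for GATA and erythroid genes (mean 0.204% against 0.345%) and above it for B lymphoid genes (0.197% against 0.103%).

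Among the GATA and ETS factors named in advance, Gata1 had the most lost regions. Gata1, the master regulator of erythroid and megakaryocytic differentiation, had 5.33 ± 0.577 peaks in wild type (SD, n = 3) and 1 peak in each of the 3 knockout samples. Of its 6 regions on chromosome X, 4 were lost, 3 inside the gene (7963876 to 7964439, 7967854 to 7968685 and 7971131 to 7971774) and 1 outside it at 7992775 to 7993685. Gata2, which acts in stem cells and mast cells, had 0 lost and 0 gained of 4 regions, with 5 ± 1 peaks in wild type and 3.67 ± 0.577 in knockout. Spi1, encoding the myeloid factor PU.1, had 0 lost and 0 gained of 11, with 12.3 ± 0.577 and 11 peaks. Ets1, a lymphoid ETS factor, gained 2 of 20 regions, both inside the gene on chromosome 9 (32660403 to 32660890 and 32726608 to 32727070), with 14 ± 1 peaks in wild type and 18 ± 1 in knockout (SD, n = 3 each). Fli1 lost 1 and gained 1 of 26 regions, with 21 ± 2 peaks in wild type and 17.7 ± 0.577 in knockout. Erg lost 1 of 36, with 28 ± 1 and 28.7 ± 2.52 peaks. The exact test of a single region for 3 samples against 3 cannot go below p = 0.1, so no single region here has a passing p of its own. In the per-gene search over regions described below, none of these factor genes passed.

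**Figure D4:**
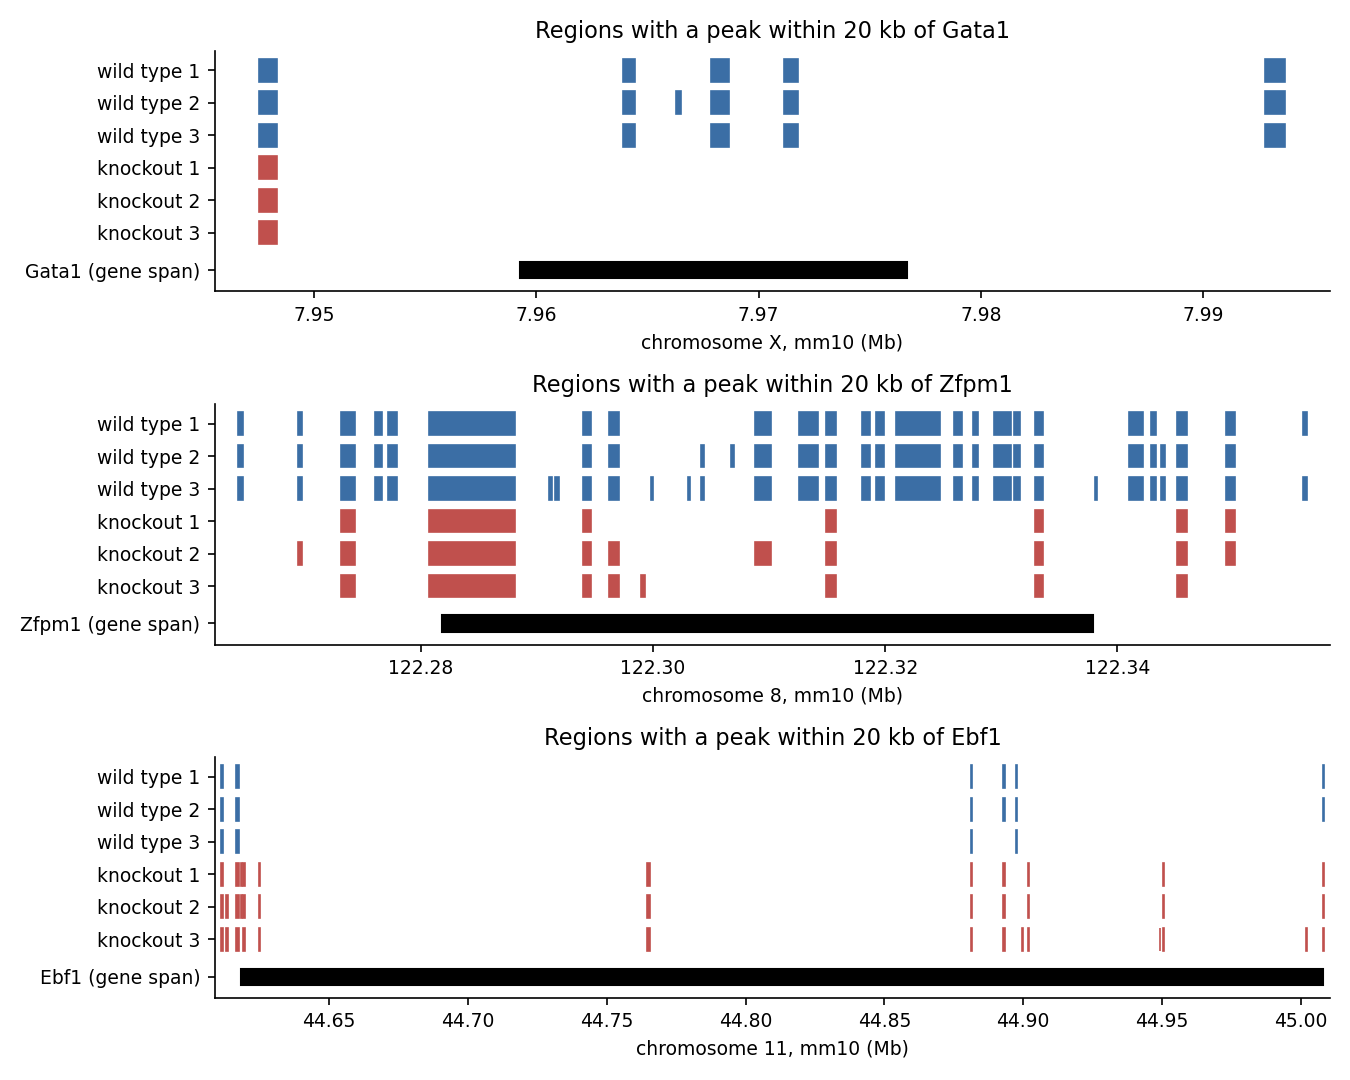
Consensus regions with a peak in each sample (wild type in blue, knockout in red, whole region drawn wherever a sample had a peak in it) within 20 kb of Gata1, Zfpm1 and Ebf1, by mm10 position in Mb; black bars are gene spans. Of the regions shown, 4 of 6 at Gata1 and 13 of 33 at Zfpm1 were lost, and 5 of 16 at Ebf1 were gained.

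Lost and gained regions lay mostly away from gene ends. Of lost regions, 6.80% (95% Wilson interval 6.27 to 7.37) lay within 1 kb of an end of a protein-coding gene, as did 7.32% (6.51 to 8.22) of gained regions and 34.2% (33.7 to 34.7) of regions with a peak in all 6 samples. Against the regions in all 6 samples, the odds ratio was 0.141 (0.128 to 0.154) for lost and 0.152 (0.134 to 0.173) for gained regions. Regions in all 6 samples were wider (median 740 bp against 444 bp for lost and 477 bp for gained), and a wider region reaches a gene end more easily. These odds ratios were not matched on width, so they do not set genotype apart from width. The difference between lost and gained regions did not pass Fisher's exact test over regions (odds ratio 0.924, 0.793 to 1.08, adjusted p = 0.323). That comparison changed with the setting, reaching 0.849 without wild-type sample 1 (exact p = 0.0242) and 0.835 with 500 bp windows around peak centres (exact p = 0.0139), and turning to 1.13 with a gene end window of 2.5 kb (exact p = 0.0436). Inside protein-coding genes lay 62.3% of lost, 54.1% of gained and 69.1% of regions found in all 6 samples.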

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

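The alternatives were chosen before the data were examined, except regions of at least 400 bp, width strata, genes as the unit and all settings of the per-gene search, which were chosen after seeing the data. Lost regions numbered 4096 with the widest 50% of peaks, 4677 with the same number of peaks per sample, 13301 when 2 of 3 samples sufficed and 4837 for regions of at least 400 bp; gained regions numbered 1848 with the widest 50% and 5651 when 2 of 3 sufficed. Fewer peaks, looser calls or fewer regions by construction moved these counts. With samples left out in turn they ranged from 8445 to 10326 and from 3784 to 5047. List calls fell to 3 with the widest 50% of peaks; the cause was not tested. The odds ratio of gene ends in lost against gained regions was 0.849 to 0.981 with samples left out in turn, past the threshold only without wild-type sample 1 (0.849), 0.835 with 500 bp windows and turned to 1.13 with a 2.5 kb window; the cause was not tested. Genes with an excess numbered 16 to 29 with samples left out in turn, the most without knockout sample 2, 11 with the widest 50% of peaks, 39 when peaks had to cover 50% of a region and 33 within 50 kb; the cause was not tested. Of 17 alternatives, the lost call of GATA and erythroid genes (odds ratio 2.81 to 5.99) and the gained call of B lymphoid genes (4.48 to 11.5) held in 17, that of megakaryocyte genes in 16, and those of fewer losses in 15 (B lymphoid), 14 (ETS) and 11 (granulocyte and monocyte). Lists whose peak shares did not overlap between genotypes numbered 9 to 11 with samples left out in turn, 11 with the widest 50% of peaks or by nearest gene and 6 within 50 kb; the cause was not tested. Fewer losses near T and NK genes passed in 4 alternatives, of which 3 left out a sample and 1 asked peaks to cover 50% of a region (0.135), more gains near them passed with the widest 50% of peaks (6.07), and more losses near stroma and endothelium genes passed without wild-type sample 3 (3.16). When 2 of 3 samples sufficed, fewer losses near housekeeping genes (0.335) and fewer gains near GATA and erythroid genes (0.321) also passed.

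Sample numbers did not pair the samples (same-number correlations of deviations -0.0233, 0.00465 and 0.0201, all below 0.1, and not every sample correlated best with its own number). With a replicate block the difference in peaks stayed at -10953, with an exact sign-flip p of 0.25, the smallest for 3 pairs, and lost and gained counts stayed at 8042 and 3566 by construction. All motif tests and their alternatives were not run, as no genome sequence was used. Unknown depth limits every count of absent peaks.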

Other observations

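The per-gene search, the split count of all separated regions, the tests of gained regions, of lineage members, of B lymphoid against other lineage genes and both tests of Xist and Firre were chosen only after the result was seen.

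Beyond the fixed lists, each of 16985 protein-coding genes was tested for an excess of lost or gained regions in or within 20 kb (one-sided exact hypergeometric test over regions, which are not replicates, with Benjamini-Hochberg adjustment). An excess of lost regions was found for 3 genes. They were Hbb-bt (7 of 9) and, next to each other on chromosome 5, Htt (8 of 12) and Msantd1 (7 of 8, exact adjusted p = 0.0197), which share 7 lost regions and are not independent calls. An excess of gained regions was found for 14 genes, led by Edil3, which encodes an integrin-binding matrix protein, with 11 of 16 regions (exact adjusted p = 2.91e-08), Klhl14 with 6 of 9 and Vps8 with 8 of 21. Hdac9, a class II histone deacetylase, gained 9 of 29, Tmem108 9 of 31 and Stac 5 of 7. The total of 17 genes became 29 without knockout sample 2. The other splits of the samples gave at most 0 such genes, and the real split was the 1 of 10 with as many as 17. Such a number of splits is too few for a share under 0.05. The other splits also had far fewer separated regions, at most 455 in 1 direction, so their 0 genes say little about the 17.

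Further members of the fixed lists, outside the naming rule, serve as examples chosen after their values were seen. Their regions are already counted in the list tests, so they add no separate evidence. Slc4a1, the red cell anion exchanger, had 3.67 ± 1.15 peaks in wild type and 0 in each knockout sample, and Alas2, the erythroid enzyme of haem synthesis, 3 and 1 in every sample of each genotype. In the B lineage, Pax5 had 2.33 ± 1.15 peaks in wild type and 9 ± 1 in knockout (SD, n = 3 each), with 3 gained regions of 11.

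The first pattern weighed is the number of separated regions against the shorter knockout lists. The real split gave 11608 lost plus gained regions and 6 list calls, and the highest of the other splits gave 491 regions and 0 list calls. In both cases 1 of 10 splits was as large, and 10 splits are too few for a share under 0.05. The other splits had at most 455 regions in 1 direction, so a list could pass there only by a strong concentration. Their 0 list calls therefore say little about the 6. Gained regions were 7.84 times the highest count in one direction of any other split (455). Every other split mixes the genotypes on both sides, and none sets the shorter lists against the longer ones. The ratio therefore does not show how many gained regions shorter lists alone would leave. Away from the fixed lists, the ratio of lost to gained regions was 2.24 and became 0.976 with the same number of peaks per sample, but equal lengths bring this ratio near 1 whatever the cause, so it does not decide whether list length is the source of the excess of losses. Whether the lists are short because of depth, library quality or biology stays open, since no read numbers were used.

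The second pattern is the loss near erythroid and megakaryocyte genes with the gain near B lymphoid genes. List length is argued against as the source near GATA and erythroid genes. Lost regions there were 3.38 times (2.66 to 4.25) the number at regions of the same wild-type width elsewhere. A few genes with many regions are argued against for the same list. Of its 26 members, with neighbours counted as 1, 24 (92.3%) had a lost region, against a median of 50% in matched random lists. The pooled share of lost regions also stood apart (p = 2.0e-04 in a permutation test against random gene lists, the smallest the draws can give). Genes with many regions weigh most in that share, so it does not decide this alone. Near megakaryocyte and platelet genes the width-matched ratio was 1.69 (1.04 to 2.58), with a lower bound close to 1. These Poisson intervals take lost regions as independent and may be too narrow. Of the 21 lost regions near megakaryocyte and platelet genes, 6 lay at Rab27b, so this interval does not settle an excess there. A smaller share of erythroid and megakaryocytic progenitors and a change within them cannot be told apart, since both would give the 33 of 39 members (84.6%, neighbours counted as 1; 48.7% in matched random lists) with a lost region, among them Hbb-bt with 9 peaks in each wild-type sample and 1.33 ± 0.577 in knockout. Gained shares were 18.1% near B lymphoid genes, 2.12% near granulocyte and monocyte genes (odds ratio 10.2, 3.41 to 30.6) and 7.02% near T and NK genes (2.93, 0.955 to 8.98), but a region already open in wild type cannot be gained, so these values do not decide whether fewer erythroid cells raised the other lineages alike. More B lineage cells stay open and untested; lineage depletion removes mature cells of both lineages, and 1 gene of the erythroid list, Gata2, is also in the mast cell list.

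The third pattern concerns wild-type sample 1, which had 0 peaks inside Xist, the RNA gene that silences an X chromosome, where each of the other samples had 3, and 1 inside Firre, where the others had 8 to 10. A male source is argued against by 0 peaks within 20 kb of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y, which also held in the other samples, while all 4 of their X-linked partners had peaks there. The labels do not give the sex, so no known male sample shows that such peaks would be called. Elsewhere on chromosome Y the other samples had 8 to 13 peaks and wild-type sample 1 had 5. A generally weaker list is argued against, since a search of 26581 genes for regions missing there only, matched on width, found an excess at 6, all at Firre (exact adjusted p = 1.43e-08) or around Xist (0.00379), while the same search found 0 genes in each other sample, including knockout sample 3 with 2252 such regions against 446. Cells with a single X chromosome may be a candidate source, and this was not tested. Without that sample there were 10326 lost and 3895 gained regions and 6 list calls.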
